A study of Mus musculus with 10 samples.

How the data were processed

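Per the labels, whole mouse oviducts were collected 8 h after hCG, those of 3 animals were pooled per sample, and total RNA was labelled with biotin through the Affymetrix whole-transcript kit. The 10 arrays fall into 5 PR+/- and 5 PRKO by the genotype label, and each is a separate pool, so p-values measure the spread between pools. The data used were the table of processed values deposited by the authors, with 1 value per probe set and array. Its log2 scale was inferred from the deposited values, since no label states it: they lie between 1.09 and 13.6, which is the range of log2 scanner signal, and folds hold only if that is so. The arrays were processed in Partek, per the submitters' processing notes; its version, the background correction, the normalization and the summary of probes are not given in the sources used here. The medians of PR+/- replicates 1 to 5 were 5.20, 5.20, 5.24, 5.23 and 5.24 and those of PRKO replicates 1 to 5 were 5.22, 5.23, 5.26, 5.28 and 5.28, so the arrays were already brought to a common level and were not normalized again. Genes had not been centred. No pair of arrays held identical values (highest correlation 0.9964).

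Probe sets were named through a table of the platform's annotation. Of 35557 rows, 21789 were paired with 1 gene symbol, 1621 with several and 12147 with none in that table, and rows of the last 2 kinds named no gene. Symbols were checked through gene IDs against a table of mouse genes of the GRCm38 assembly, used only for names and for the order of neighbouring genes. It held the ID of 21698 rows, none of which changed symbol, and the other 91 kept the annotation's symbol. Where a gene had several probe sets (999 genes), the one with the highest mean over all arrays stood for it, which left 19938 genes. Disagreement between the probe sets of a named gene is given beside it. No filter on dim signal was applied, because the table holds no background or detection values. Low signals may therefore lie near background, where an array understates a fold change.

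The genotypes were compared with limma 3.58.1 in R 4.3.3, in a linear model with genotype as its term and moderated variances (8 residual and 6.08 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Values with ± in the text are SE of the log2 difference unless SD is stated. The single-value comparisons of Pgr signal and interquartile range used two-sided exact permutation tests. Each of 30 gene lists was tested with limma's camera at its preset correlation of 0.01, adjusted over the 30 lists. Camera with a correlation estimated per list and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run beside it. Of the 11 lists called, 3 were called with an estimated correlation and fry called 9 of the 30. The adjusted p given for a list member is that over all genes, unless it is said to be adjusted over the list alone.

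The sample groups, the test, the gene lists, most of the alternatives and the rule for naming genes were fixed before the data were examined. Some list members (Itga8, Edn3, Agtr2, Ptgfr, Prlr, Des, Actg2, Myocd and Adamts1) were recalled from published work on this study, so their lists are not independent evidence of direction. The rule named Pgr, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose values did not overlap between genotypes, and up to 4 called members of each list by smallest p. Predicted loci, olfactory and vomeronasal receptors, microRNAs and small nucleolar RNAs were counted but passed over in naming. Members named outside this rule, with their values, were chosen after the values were seen. The replicate numbers of the labels did not meet the check set for pairing the samples, and the test did not use them.

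The alternatives were quantile normalization, centring on each array's median, removal of the dimmest 30% or 50% of probe sets, the mean of a gene's probe sets, a test of every row, a variance trend with robust moderation, no moderation, array weights, the replicate number as a block, each array left out in turn, other list tests, and other thresholds. After the data were seen, 5 were added: each array's interquartile range as a covariate, cyclic loess normalization, leaving out PRKO replicates 1 and 5, which had the lowest correlation with their group, leaving out PR+/- replicate 4 and PRKO replicate 3, which had the highest ovarian marker signal, and leaving Pgr out of the estrogen-responsive list.

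The procedure was tested on simulated data drawn from the 19938 genes' means and spreads, with 50 genes changed at each of 4 sizes. It recovered 26% of those changed 1.25-fold, 82% at 1.5-fold, 98% at 2-fold and 100% at 3-fold, and 12 of its 165 calls were false. In a simulation of the 30 lists, the 1 shifted list was called and 0 of the others were. Both simulations drew each gene independently and with the same spread in both genotypes. In the data the estimated correlation was 0.34 for the smooth muscle list and 0.42 for the ovarian list. False calls from correlation between list members were therefore not tested. The figures were drawn with matplotlib 3.10.9.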

Results

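Gene expression was measured in whole oviducts of prepubertal mice whose progesterone receptor gene, Pgr, was disrupted by a lacZ insertion. Homozygous animals, which lack both isoforms of the receptor and are called PRKO, were set against heterozygous PR+/- controls, which are fertile. All animals received 5 IU of equine chorionic gonadotropin (eCG), a hormone that drives follicle growth, and then 5 IU of human chorionic gonadotropin (hCG), which triggers ovulation. Oviducts were taken 8 h after hCG, and those of 3 animals were pooled for each array, which gave 5 arrays and 15 animals per genotype. Biotin-labelled cRNA was hybridised to Affymetrix whole-transcript arrays, and 19938 named genes were tested. The comparison asks which oviduct transcripts differ without the progesterone receptor 8 h after the ovulatory trigger. No array was taken before hCG, so differences already present by then cannot be told from those that arose after it. Since each value is a log2 signal from tissue pools, the number of arrays limits the precision. The median gene had a 95% interval of ± 0.20 around its log2 difference.

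The arrays of a genotype resembled each other closely, with pairs of arrays correlated over genes at 0.9945 to 0.9964 in PR+/- and at 0.9877 to 0.9924 in PRKO. PRKO pools varied more. The median SD of a gene was 0.113 on the log2 scale in PR+/- and 0.167 in PRKO, and 74.7% of genes had the larger SD in PRKO. The interquartile range of an array's log2 values was 3.43 ± 0.045 in PR+/- and 3.29 ± 0.109 in PRKO (SD, n = 5 each, two-sided exact permutation p = 0.0238), and it was lowest, at 3.13, in PRKO replicate 5. Within PR+/- it went down with the replicate number, from 3.484 in replicate 1 to 3.374 in replicate 5, while in PRKO it did not follow the number. PRKO replicate 2, at 3.415, lay within the span of PR+/-. Ovarian transcripts stood apart on 1 array of each genotype. The signal of Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, was 7.04 in PR+/- replicate 4 and 7.10 in PRKO replicate 3, against 3.05 to 4.68 on the other 8 arrays.

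Pgr itself was lower on every PRKO array than on any PR+/- array. Its log2 signal was 7.42 ± 0.11 in PR+/- and 6.36 ± 0.037 in PRKO (SD, n = 5 each), so PRKO oviducts held 48.0% of the heterozygous signal (two-sided exact permutation p = 0.00794, the smallest that 252 arrangements can give). The limma adjusted p was 1.00e-06. The array reads this gene through probe set 10583179, and which of its probes lie within transcript still made from the disrupted allele was not examined here. The drop therefore goes with the genotype labels without measuring how much functional transcript was left.

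**Figure D1:**
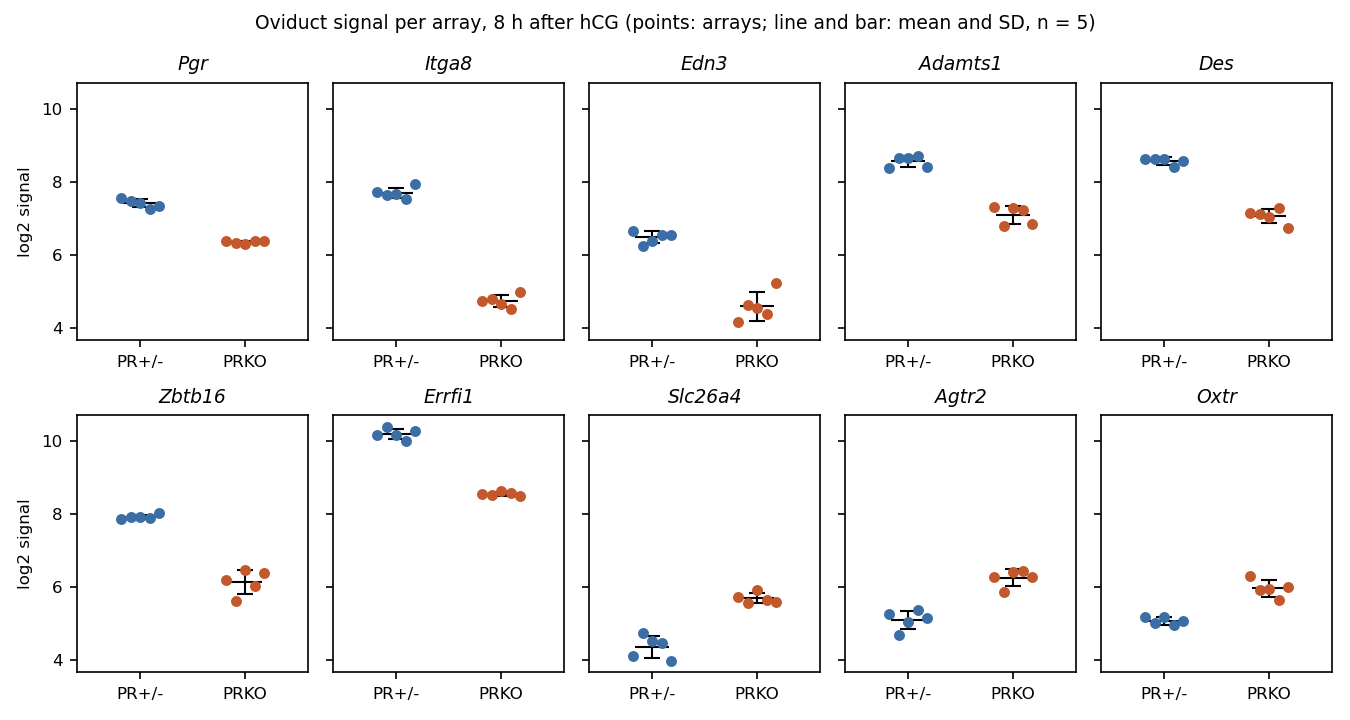
Log2 signal of 10 genes on each array of PR+/- (blue) and PRKO (orange) oviducts, 8 h after hCG. Points are arrays of 3 pooled animals, and lines with bars give the mean and SD (n = 5). In each panel the points of the genotypes do not overlap.

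Among called genes, more were lower than higher in PRKO oviducts, while the median log2 change of all tested genes was 0.03. The deepest fall among the genes that the naming rule admits was that of Itga8, the integrin alpha 8 subunit found on smooth muscle and other mesenchymal cells, with a log2 change of -2.96 ± 0.098 (SE, n = 5 against 5) and a 7.79-fold lower signal. Maob, the mitochondrial monoamine oxidase B, was 4.59-fold lower, Dpep1, a membrane dipeptidase, 4.26-fold, Sbspon, a secreted matrix protein, 3.77-fold, and Edn3, the peptide endothelin 3, 3.70-fold. The largest rises by the same rule were those of Slc26a4, the anion exchanger pendrin, at 2.52-fold (log2 1.33 ± 0.13), and Agtr2, an angiotensin II receptor, at 2.23-fold (1.16 ± 0.13). Padi4, which converts arginine to citrulline in histones, followed at 2.12-fold. Among 19938 genes, 988 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, of which 771 fell and 217 rose. At an unadjusted p under 0.05 the split was closer, with 2208 lower and 2007 higher.

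Other deep falls were those of Cwh43, a factor in lipid anchor synthesis (3.65-fold lower), the transcription factor Zbtb16 (3.46-fold), Cyp1b1, a cytochrome P450 that hydroxylates estrogens (3.43-fold), and the amino acid transporter Slc7a8 (3.27-fold). Rgs2, which shortens signalling through Gq proteins, was 3.21-fold lower, Errfi1, a feedback inhibitor of the epidermal growth factor receptor, 3.12-fold, and the transcription factor Tcf23 2.99-fold. The adjusted p of these 12 deepest falls was at most 1.40e-04. Rises were smaller. They took in Chil1, a chitinase-like glycoprotein (2.0-fold), Pln, the inhibitor of the sarcoplasmic calcium pump (1.97-fold), Oxtr, the oxytocin receptor (1.85-fold), Cdh16, a cadherin (1.83-fold), Adamtsl3, a secreted matrix glycoprotein (1.83-fold), and Apobec2, a muscle protein of the cytidine deaminase family (1.79-fold). Crabp2, which carries retinoic acid, rose 1.64-fold, the arginase Arg1 1.53-fold, and the transporter Slc16a14 by a log2 change of 0.68. A change of at least 1.5-fold was passed by 231 genes that fell and 17 that rose, and one of at least 2-fold by 57 and 4. The 5 values of each genotype did not overlap for 853 of the 988 genes. They did not overlap for 7.20% of all tested genes, where chance gives 0.794%.

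The counts of called genes changed when single arrays were left out, and each such fit had fewer samples. Leaving out a PR+/- array gave 581 to 754 called genes. Leaving out a PRKO array, from the group with the larger spread, gave 763 to 1165. Without PR+/- replicate 1, 581 genes were called (84 rose, 497 fell), and without PR+/- replicate 2, 598 (93 rose, 505 fell), while the count of rises also moved to 126, 132, 136 and 330 without PR+/- replicate 3, PR+/- replicate 4, PRKO replicate 3 and PRKO replicate 4. With each array's interquartile range as a covariate, 322 genes were called, of which 58 rose and 264 fell, and 30 of the 83 named genes lost their call: Chil1, Adamtsl3, Crabp2, Ptgs2, Cfap43, Kcnma1, Ltf, Igfbp6, Itga9, Pgrmc2, Ano1, Atp1b1, Wnt2b, Gli1, Sfrp2, Ccl9, Cxcl17, Slc2a4, Pnpla2, Tnnc2, Emcn, Pecam1, Msln, Krt19, Myc, Hlf, Kbtbd3, Trpc6, Tmem123 and Rpsa. Wnt2b, Ccl9, Myc, Krt19 and Pnpla2 then had log2 changes of -0.37, 0.33, -0.21, -0.18 and -0.23 (adjusted p 0.111, 0.234, 0.515, 0.580 and 0.406), all of them more than 1.5 times closer to 0 than without the covariate. The covariate itself differed between genotypes. With it, the median SE of the 771 genes that fell grew from 0.092 to 0.115, and their median log2 change went from -0.46 to -0.41. A call lost there may therefore reflect lower precision. Quantile normalization ended 6 of the 83 calls and cyclic loess normalization 5.

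**Figure D2:**
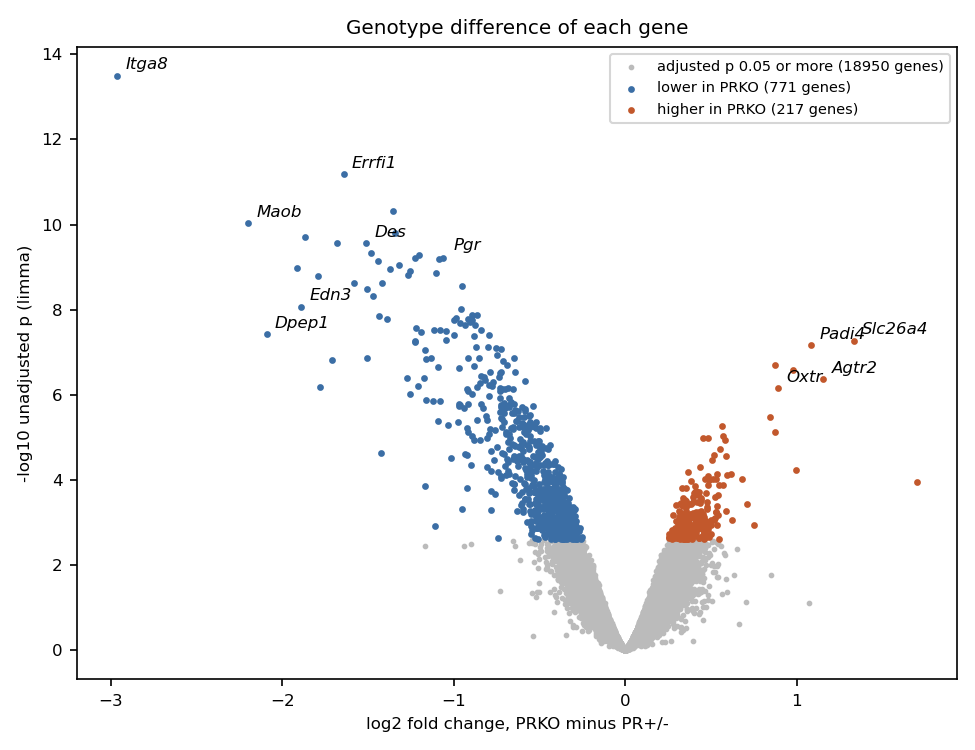
Log2 fold change of each tested gene (PRKO minus PR+/-, horizontal axis) against the minus log10 of its unadjusted limma p (vertical axis). Blue points are the 771 genes that fell and orange points the 217 that rose at adjusted p under 0.05, and grey points are the other 18950 genes. The genes furthest from 0 lie on the left, with Itga8 at -2.96.

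Genes of the smooth muscle contractile apparatus fell together. Of 24 measured members, 19 fell, none rose and 5 did not pass over all genes, while 20 fell and 1 rose when adjusted over the list alone. Des, the muscle intermediate filament desmin, fell by 1.51 ± 0.096 on the log2 scale (2.84-fold lower), Actg2, the gamma actin of visceral smooth muscle, by 1.20 ± 0.081 (2.30-fold), Pgm5, a protein of muscle adhesion sites, by 0.96 ± 0.080 (1.94-fold), and Cnn1, the actin-binding calponin, by 0.92 ± 0.080 (1.89-fold). Myocd, the coactivator that drives smooth muscle genes, also fell (1.90-fold lower), as did Myh11, the smooth muscle myosin heavy chain (1.65-fold), and Acta2, its alpha actin (1.52-fold). With a median log2 change of -0.57, camera placed the list below other genes at an adjusted p of 1.35e-25, which was 0.0381 with an estimated correlation. The members past neither test were Kcnmb1, Synm and Casq2, with log2 changes of -0.12, 0.11 and -0.04. Pcp4, a calmodulin-binding peptide, had a log2 change of 0.45 and was the member that rose in the adjustment over the list alone. Des, Actg2 and Myocd here, and Itga8, Edn3, Agtr2, Ptgfr and Adamts1 in other lists, were recalled from published work on this study when the lists were drawn up, so those counts are not independent evidence.

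Ligands and receptors that act on contraction moved in both directions. Edn3 fell (log2 -1.89 ± 0.16), as did Ptgfr, the prostaglandin F receptor (-0.92 ± 0.13), and Ptger1 and Ptger2, receptors for prostaglandin E (-0.51 ± 0.12 and -0.45 ± 0.11). Agtr2 and Oxtr rose, as given above. Of 28 measured members, 2 rose, 4 fell and 22 did not pass, with the same counts of 2 and 4 when adjusted over the list alone, and camera gave an adjusted p of 0.689. The endothelin receptor gene Ednrb had a log2 change of 0.32 (adjusted p = 0.130) and the ligand Edn1 one of -0.03. Among 13 genes of prostaglandin synthesis and transport, 1 fell, Ptgs2, the inducible cyclooxygenase (-0.62 ± 0.10, 1.53-fold lower), whose log2 change was -0.56 and whose call was lost, at an adjusted p of 0.0740, with the interquartile range as a covariate. The other 12 did not pass, while 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.147).

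The extracellular matrix was lower in part. Among 32 collagens and structural matrix genes, 14 fell and 18 did not pass, and 17 fell and 1 rose when adjusted over the list alone. Postn, the matricellular protein periostin, was 2.70-fold lower (log2 -1.43 ± 0.12), Col12a1, a collagen that decorates fibrils, 2.40-fold (-1.26 ± 0.092), Bgn, the proteoglycan biglycan, 2.06-fold (-1.05 ± 0.096), and Lama4, a laminin chain of basement membranes, 1.73-fold (-0.79 ± 0.097). The fibrillar collagen genes Col1a1 and Col3a1 had log2 changes of -0.11 and -0.28 and did not pass over all genes. Its median was -0.28 (camera adjusted p = 5.78e-10, and adjusted p = 0.0979 with an estimated correlation). Of 35 matrix proteases and their inhibitors, 8 fell and 27 did not pass, and 14 fell and 1 rose when adjusted over the list alone. Adamts1, a secreted protease that cleaves versican, was 2.77-fold lower (-1.47 ± 0.12), its relative Adamts5 1.80-fold and the inhibitor Timp3 1.77-fold, and Reck, another inhibitor, fell by 0.58. That list's median was -0.15 (camera adjusted p = 2.67e-06, and adjusted p = 0.0681 with an estimated correlation).

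Integrins, the receptors that bind cells to this matrix, split. Of 20, 8 fell, 1 rose and 11 did not pass, and 8 fell and 4 rose when adjusted over the list alone. Besides Itga8, those that fell included Itgb5 (1.66-fold lower, log2 -0.73 ± 0.080), Itgb3 (1.62-fold, -0.69 ± 0.10) and Itga9 (1.49-fold, -0.57 ± 0.10). Itga4, an alpha subunit of leukocytes and other cells, rose (0.34 ± 0.088). The list's median log2 change was 0.02 and its mean -0.25, and camera placed it downward at an adjusted p of 0.0334, against adjusted p = 0.323 with an estimated correlation. Without PRKO replicate 1, 2 or 5 the adjusted p was 0.0605, 0.0513 and 0.0789.

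Genes described as PGR targets in uterus or ovary were lower in part. Of 21 measured, 7 fell and 14 did not pass, and 10 fell and 2 rose when adjusted over the list alone. Zbtb16 fell by 1.79 ± 0.13 on the log2 scale, Adamts1 by 1.47 ± 0.12, and Cited2, a transcriptional coregulator, by 1.04 ± 0.15 (2.05-fold lower). Fkbp5, a chaperone of steroid receptors, was 2.38-fold lower (limma adjusted p = 1.83e-04). The transcription factor genes Gata2 and Nr2f2 and the interleukin receptor gene Il13ra2 fell by 0.65, 0.38 and 0.55. Ihh, a uterine epithelial target, had a log2 change of -0.34 (adjusted p = 0.0666), and Hand2, a stromal one, -0.12. The list's median was -0.15 (camera adjusted p = 3.38e-04, and adjusted p = 0.0359 with an estimated correlation).

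Glucocorticoid-responsive genes showed a larger shift. Of 17 measured, 8 fell and 9 did not pass, and 11 fell when adjusted over the list alone. Errfi1 fell by 1.64 ± 0.080, Sult1a1, a phenol sulfotransferase, by 1.34 ± 0.082 (2.53-fold lower), and Hif3a, a hypoxia-inducible factor subunit, by 1.32 ± 0.092 (2.49-fold). Zbtb16 and Fkbp5 belong to this list as well as to that of PGR targets. Tsc22d3, a glucocorticoid-induced leucine zipper protein, was 1.71-fold lower and the kinase Pdk4 1.37-fold. The list's median was -0.46 (camera adjusted p = 5.10e-14, and adjusted p = 0.0162 with an estimated correlation).

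**Figure D3:**
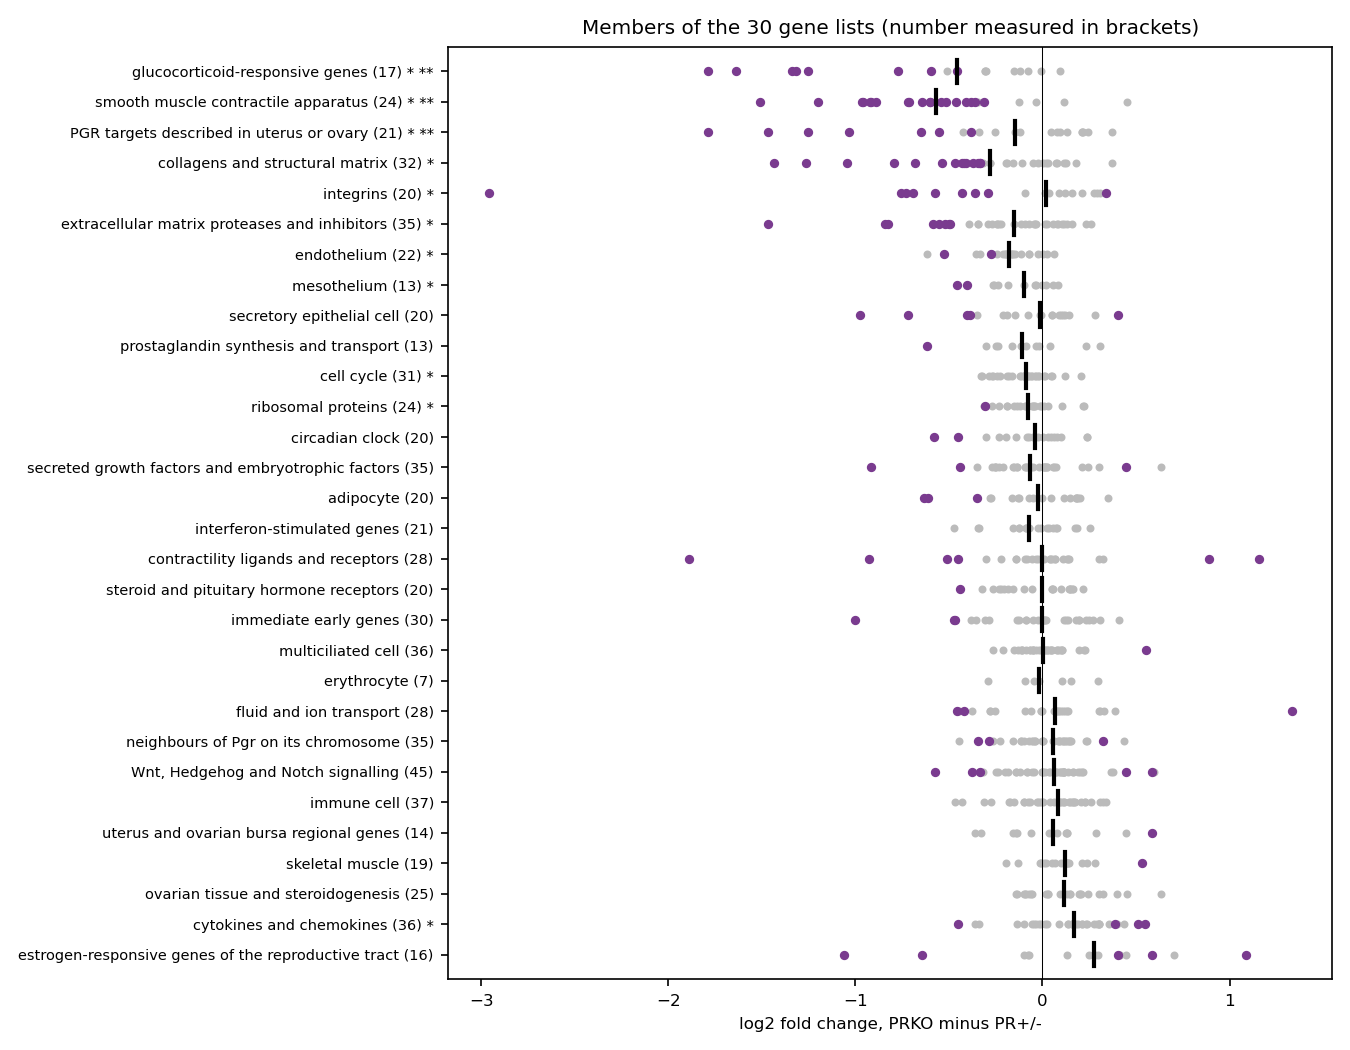
Log2 fold change (PRKO minus PR+/-, horizontal axis) of each measured member of the 30 gene lists, sorted by the mean of the list's members. Purple points passed adjusted p 0.05 over all genes, grey points did not, and the black bar is the list's median. A single star marks the 11 lists called by camera, and a double star the 3 that were also called with an estimated correlation. The glucocorticoid-responsive, smooth muscle and PGR target lists carry both marks.

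Estrogen-responsive genes of the reproductive tract included Pgr, whose fall is set by the genotype itself. Padi4, Wnt7a, a Wnt ligand of Müllerian epithelium (log2 0.58), and Ltf, the secreted iron-binding protein lactoferrin (0.40), rose, and besides Pgr only Greb1, an estrogen receptor cofactor (1.57-fold lower), fell. Of 16 measured, 3 rose, 2 fell and 11 did not pass, and 6 rose and 2 fell when adjusted over the list alone. The median was 0.28 (camera adjusted p = 0.0766). Without Pgr, a test added after the data were seen, 3 of 15 rose, 1 fell and 11 did not pass, and 5 rose and 1 fell when adjusted over the list alone. Camera then called the list upward at an adjusted p of 0.00609, against adjusted p = 0.106 with an estimated correlation. With Pgr kept, it was called upward in several alternatives, at an adjusted p of 0.0474 without PR+/- replicate 1 and 0.0325 without PRKO replicate 5, and its adjusted p then spanned 0.00937 to 0.323 over the alternatives. Among 20 receptors for steroid and pituitary hormones, 1 fell, the membrane progesterone-binding protein gene Pgrmc2 (log2 -0.44 ± 0.095), and 19 did not pass (0 rose and 2 fell when adjusted over the list alone, camera adjusted p = 0.298).

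The main epithelial cell types were followed through marker lists. In whole oviducts other cells, muscle included, may express the same genes, so a change need not lie in the epithelium. Of 36 multiciliated cell genes, 1 rose, Cfap43, a protein of the ciliary axoneme (1.47-fold, 0.55 ± 0.087), and 35 did not pass (1 rose when adjusted over the list alone). The list's median was 0.00 and camera gave an adjusted p of 0.907, but 0.0110 upward with the interquartile range as a covariate, a setting in which the call of Cfap43 was lost at an adjusted p of 0.0556. The gene's other 4 probe sets had log2 changes of 0.35 to 0.70. Of 20 secretory cell genes, 4 fell and 1 rose. Cldn3, a tight junction claudin, was 1.97-fold lower (-0.98 ± 0.14), Gpx3, a secreted glutathione peroxidase, 1.64-fold (-0.72 ± 0.098), and the potassium channel gene Kcnma1 1.31-fold, though its second, dimmer probe set had a log2 change of -0.04, and with the mean of probe sets the gene's was -0.22 and not called (adjusted p = 0.117). Krt19, a keratin, fell by 0.40, and Ltf rose. The other 15 did not pass, 2 rose and 4 fell when adjusted over the list alone, and camera gave an adjusted p of 0.165. The call of Krt19 was lost when any array but PRKO replicate 1 or 2 was left out (adjusted p 0.0679 to 0.120), and that of Ltf without any of PR+/- replicates 1 to 3 or PRKO replicates 1, 3 and 4 (0.0545 to 0.0835).

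Among 28 genes of fluid and ion transport, Slc26a4 rose, Atp1b1, a subunit of the sodium pump (-0.46 ± 0.095), and Ano1, a calcium-activated chloride channel (-0.42 ± 0.086), fell, and 25 did not pass (3 rose and 6 fell when adjusted over the list alone). Both falls were smaller with the interquartile range as a covariate, at log2 -0.27 and -0.28, and were no longer called there, at adjusted p of 0.302 and 0.260. The transport list had a median of 0.06 and a mean of 0.02, whereas camera leaned downward (adjusted p = 0.907). Of 35 secreted growth factors and embryotrophic factors, Fgf7, a fibroblast growth factor made by stroma for epithelium, fell by 0.92 ± 0.11 (1.89-fold lower), Igfbp6, which binds insulin-like growth factors, fell by 0.44 ± 0.093, and Inhbb, an activin subunit, rose (0.44 ± 0.11). The call of Inhbb was lost without any of PR+/- replicates 2 to 5 or PRKO replicates 3 and 4 (adjusted p 0.0578 to 0.0900). The other 32 did not pass, 1 rose and 3 fell when adjusted over the list alone, and camera gave an adjusted p of 0.0773, or 0.0317 without PRKO replicate 3.

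In Wnt, Hedgehog and Notch signalling, Wnt7a and Sfrp2, a secreted Wnt antagonist (log2 0.44), rose, and Wnt2b, a Wnt ligand (-0.57), Gli1, a transcription factor of Hedgehog signalling (-0.34), and Rspo3, which amplifies Wnt signals (-0.38), fell. The other 40 of 45 members did not pass, 3 rose and 5 fell when adjusted over the list alone, and camera gave an adjusted p of 0.848. The call of Sfrp2 was lost without PR+/- replicate 1 or 2 or PRKO replicate 3 (adjusted p 0.0509 to 0.0616), and that of Gli1 without PR+/- replicate 2 or 3 (0.0553 and 0.0619). Among 36 cytokines and chemokines, Cxcl16, Ccl9 and Cxcl17 rose (0.51, 0.55 and 0.39), Ccl6 fell (-0.45) and 32 did not pass, and 4 rose and 1 fell when adjusted over the list alone. The list's median was 0.17, and camera placed it upward at an adjusted p of 0.0124, against adjusted p = 0.377 with an estimated correlation and 0.0505 without PRKO replicate 1. With the interquartile range as a covariate the list's median was 0.07 and its camera adjusted p 0.309. It stayed called with quantile normalization (adjusted p = 0.0378) and with the dimmest 50% removed (0.00323). The call of Cxcl17 was lost when any array but PRKO replicate 4 or 5 was left out (adjusted p 0.050 to 0.106). No member passed among 21 interferon-stimulated genes or 37 immune cell genes in limma, over all genes or adjusted over the list alone, where 3 and 11 had an unadjusted p under 0.05 (camera adjusted p = 0.468 and 0.498).

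Markers of other cells and tissues in the pooled organ were followed in the same way. Of 22 endothelial genes, Emcn, the sialoprotein endomucin (log2 -0.53 ± 0.11), and Pecam1, an endothelial adhesion molecule (-0.27 ± 0.070), fell, with the same 2 falling when adjusted over the list alone, and 20 did not pass. The endothelial median was -0.18 (camera adjusted p = 7.15e-05). That list was not called with an estimated correlation (adjusted p = 0.268) or with the dimmest 50% removed (0.0600). Of 13 mesothelial genes, Msln, the surface protein mesothelin (-0.45 ± 0.10), and Krt19 fell, also when adjusted over the list alone, and 11 did not pass. Krt19 is also a member of the secretory cell list, so its fall need not lie in mesothelium. The mesothelial median was -0.10 (camera adjusted p = 0.0319, and adjusted p = 0.553 with an estimated correlation), and without PR+/- replicate 1, PRKO replicate 4 or PRKO replicate 5 the adjusted p was 0.0731, 0.0810 and 0.126. The call of Pecam1 was lost when any array but PRKO replicate 3 or 4 was left out (adjusted p 0.0526 to 0.0898), and that of Msln without PR+/- replicate 2 (0.0566). Of 20 adipocyte genes, Scd1, a fatty acid desaturase (-0.63), Slc2a4, the insulin-regulated glucose transporter (-0.61), and Pnpla2, a triglyceride lipase (-0.35), fell and 17 did not pass, with 4 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.444). The member that rose there was Plin1 (0.35). Adipoq and Lep, at PR+/- log2 signals of 2.60 and 2.72, had log2 changes of 0.19 and 0.18 and did not pass. The call of Pnpla2 was lost when any array but PRKO replicate 1 or 2 was left out (adjusted p 0.0599 to 0.0826).

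Among 19 skeletal muscle genes, Tnnc2, a troponin of fast fibres, rose (0.53 ± 0.096) and 18 did not pass, with 1 rising when adjusted over the list alone (camera adjusted p = 0.107). With the interquartile range as a covariate its log2 change was 0.33 and the call was lost (adjusted p = 0.174). No member of 25 ovarian and steroidogenic genes or 7 erythrocyte genes passed in limma, over all genes or adjusted over the list alone, and 2 of each had an unadjusted p under 0.05. Camera gave the ovarian list an adjusted p of 0.298, but 0.00568 upward without PR+/- replicate 4, the PR+/- array with the high Cyp11a1 signal. It gave the erythrocyte list, with a median of -0.02 and a mean of 0.01, an adjusted p of 0.848 upward. Of 14 genes that mark the uterus or the ovarian bursa, Wnt7a rose and 13 did not pass, while 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.815).

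Lists of general cell state were also tested. Of 30 immediate early genes, Ccn2, a matricellular growth factor (log2 -1.0 ± 0.093), Gadd45b, a stress-induced protein (-0.47 ± 0.086), and Myc, a growth-promoting transcription factor (-0.47 ± 0.11), fell and 27 did not pass, with 3 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.444). The call of Myc was lost without any of PR+/- replicates 1 to 4 or PRKO replicates 1, 3 and 5 (adjusted p 0.0587 to 0.0814). Of 20 circadian clock genes, Nfil3 (-0.58) and Hlf (-0.45), related transcription factors of the clock's output, fell, also when adjusted over the list alone, and 18 did not pass (camera adjusted p = 0.162). Without PR+/- replicate 1 the adjusted p of Hlf was 0.0565. No member of 31 cell cycle genes passed in limma, over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05. The cell cycle median was -0.09 (camera adjusted p = 0.0141, and adjusted p = 0.514 with an estimated correlation), and the adjusted p was 0.0887 without PR+/- replicate 4 and 0.0829 without PRKO replicate 1.

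Of 24 ribosomal protein genes, 1 fell, Rpsa, a protein of the small subunit (log2 -0.31 ± 0.082), and 23 did not pass, with 2 falling and 1 rising when adjusted over the list alone. The median was -0.08 (camera adjusted p = 0.0334, and adjusted p = 0.354 with an estimated correlation), and the adjusted p was 0.0753, 0.0659 and 0.0747 without PR+/- replicate 2, PRKO replicate 2 and PRKO replicate 3. The call of Rpsa was lost when any array but PRKO replicate 1 was left out (adjusted p 0.0532 to 0.127). Its other 4 probe sets had log2 changes of -0.14 to -0.28. In limma's test of every row none of them passed, and neither did the probe set used here (adjusted p = 0.0902). With the mean of probe sets the gene's log2 change was -0.22 and not called (adjusted p = 0.106). Among 35 neighbours of Pgr on its chromosome, Kbtbd3 rose (0.32), Trpc6, a calcium-permeable channel (-0.34), and Tmem123, a membrane protein (-0.29), fell, with the same counts when adjusted over the list alone, and 32 did not pass (camera adjusted p = 0.907). The call of Tmem123 was lost when any array but PRKO replicate 2 or 4 was left out (adjusted p 0.0671 to 0.110), that of Trpc6 without any of PR+/- replicates 2 to 5 or PRKO replicates 1 and 3 (0.0644 to 0.0931), and that of Kbtbd3 without PR+/- replicate 1 (0.0506).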

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

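The tests with the interquartile range as a covariate and that of glucocorticoid exposure were chosen after the results were seen, and the explanations behind the tests of equal muscle loss and of signal compression were narrowed after their results were seen.

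Single arrays stood far from the rest of their group in 8 of 226 groups of 5 values, where chance alone gives about 11.3. The log2 signal of Agtr2 was 5.869 in PRKO replicate 2, against 6.27 to 6.433 in the other PRKO arrays. Des was 8.401 in PR+/- replicate 4, against 8.581 to 8.643. Greb1 was 8.038 in PRKO replicate 5, against 8.255 to 8.33. Gadd45b was 6.773 in PR+/- replicate 2, against 6.926 to 6.961, and Sult1a1 was 6.13 in PR+/- replicate 3, against 6.411 to 6.506. Of the mean scores of gene lists relative to PR+/-, fluid and ion transport stood at 0.066 in PR+/- replicate 2 (others -0.025 to -0.003) and interferon-stimulated genes at 0.193 in that array (others -0.092 to -0.016). The ovarian score was 0.549 in PR+/- replicate 4, against -0.183 to -0.091 in the other PR+/- arrays, and 0.693 in PRKO replicate 3. Rows of the array that the report did not name also differed between genotypes. Of 12147 probe sets absent from the annotation table, 124 passed an adjusted p of 0.05 in limma (47 rose, 77 fell), and of 1621 paired with several genes, 62 did (4 rose, 58 fell).

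More genes fell than rose in PRKO oviducts. Only 1 of 100 splits of the arrays into 5 and 5, the real one, gave as many as 988 genes, and the highest other gave 0. Every other split mixed the genotypes, so their difference widened the spread within its groups and made calls unlikely there. The splits argue against chance as the source of the count but do not exclude it. They also cannot separate genotype from a factor that follows it. Compressed signal on the PRKO arrays would raise dim genes and lower bright ones, and part of the data goes with it. With genes ranked by mean signal into 10 equal classes, 23 of the 1994 in the dimmest rose and 0 fell in limma at adjusted p under 0.05, and in the brightest 16 rose and 170 fell. With each array's interquartile range as a covariate, the median log2 change over all genes of these classes went from 0.11 and -0.05 to 0.02 and 0.01. With that trend removed, however, 82% of the 322 genes called still fell, which argues against compression as the whole cause. The 771 genes, chosen because they fell, kept 88.8% of their median size (log2 -0.46 before, -0.41 after), while their median SE grew from 0.092 to 0.115 and fewer calls were made. Quantile normalization, which gives every array the same range, called 881 genes, of which 76.96% fell, against 78.04% without it. Cyclic loess normalization called 955 genes, of which 77.28% fell. For the called genes, these shares argue against compression as the main source of the excess of falls. A smaller contribution was not excluded. DNA of the embryonic stem cell strain kept around the disrupted locus would gather called genes beside Pgr, but 4 of 83 neighbours were called, 4.82% against 4.96% of all genes (exact hypergeometric p = 0.593). Those 83 genes could never supply most of the 988 calls. With so few, a small excess beside Pgr could also be missed, so the test does not show whether such DNA was kept. An effect of the receptor's absence remains open as a hypothesis, be it direct, through altered development of the oviduct, or through its absence elsewhere in the animal. It was not tested further, and neither could batches be, since the labels give none.

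The smooth muscle list fell with a median log2 change of -0.57. Signal compression as the whole cause is argued against by a median of -0.595 with the range as a covariate. Loss of all smooth muscle cells alike would lower members alike, but the 95% intervals of 14 of 24 members excluded the list's median, and that of Des (-1.72 to -1.30) lay apart from that of Myh11 (-0.94 to -0.50). Members that other cells also express would fall less and probe sets respond unequally, so a partial or visceral loss of muscle, or lower transcription per cell, may each account for the list and were not separated.

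The glucocorticoid-responsive list fell with a median of -0.46. Its overlap with the list of PGR targets was 2 genes, and without them it was still called (median -0.31, camera adjusted p = 1.85e-10, or 0.0359 with an estimated correlation). That list does not hold every PGR target, so the remaining members may still include some. The test therefore cannot show that the shift goes beyond PGR targets. Lower glucocorticoid exposure of PRKO animals cannot be told apart from a response of these genes to the progesterone receptor itself: 16 of 17 members had a negative log2 change, as either would give, and no hormone level was measured here. That the receptor acts on genes shared with the glucocorticoid receptor may be a candidate explanation, and these data hold no test of it.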

How the results depend on the processing

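The interquartile range as a covariate, cyclic loess, the removals of pairs of arrays and the estrogen-responsive list without Pgr were chosen after the data were seen. No list or gene called in the report changed direction in its test. Pgr kept its call throughout (log2 -1.10 to -1.02), as did the smooth muscle list (adjusted p 1.68e-29 to 0.0381), the PGR target list (1.55e-05 to 0.0359) and the glucocorticoid-responsive list (3.54e-15 to 0.0162). Of the 83 named genes, 51 were called in every alternative that tested them, 32 lost the call in at least 1 and 0 changed direction. Over the single arrays left out, 581 to 1165 genes were called, 84 to 330 rose and 497 to 882 fell, with adjusted p of 0.0157 to 0.0789 for integrins, 0.00224 to 0.0505 for cytokines, 0.00168 to 0.0887 for cell cycle, 0.0106 to 0.126 for mesothelium and 0.0158 to 0.0753 for ribosomal proteins. The rises were 142 with median centring, 133 with every row tested and 129 without variance moderation. Calls numbered 412 (44 rose, 368 fell) at adjusted p under 0.01 and 4215 (2007 rose, 2208 fell) at unadjusted p under 0.05, and 61 genes passed 2-fold. Quantile normalization gave integrins 0.0939, mesothelium 0.151 and ribosomal proteins 0.675, and cyclic loess gave them 0.118, 0.177 and 0.813. With the dimmest 30% removed, 7 lists were called, with integrins and mesothelium at 0.222 and cell cycle and ribosomal proteins at 0.293. With 50% removed, cell cycle had 0.988, endothelium 0.0600, mesothelium 0.449 and ribosomal proteins 0.595. Both filters leave fewer genes to compare with. Array weights gave integrins 0.0780 and mesothelium 0.0784. With an estimated correlation 3 lists were called, with adjusted p of 0.0681 for matrix proteases, 0.0979 for collagens, 0.323 for integrins, 0.377 for cytokines, 0.514 for cell cycle, 0.268 for endothelium, 0.553 for mesothelium and 0.354 for ribosomal proteins. Fry gave cytokines 0.0661, cell cycle 0.194 and mesothelium 0.203. With the range as a covariate, 322 genes were called (58 rose, 264 fell), and integrins had 0.117, cytokines 0.309, cell cycle 0.0730, mesothelium 0.722 and ribosomal proteins 0.238. Without PRKO replicates 1 and 5, 141 genes rose, and integrins had 0.162, cytokines 0.0861, cell cycle 0.262 and mesothelium 0.146. Without PR+/- replicate 4 and PRKO replicate 3, 562 genes were called (73 rose, 489 fell), with cell cycle at 0.0569 and ribosomal proteins at 0.0657, and here fewer samples entered the fit. Lists not called in the report were called for estrogen-responsive genes in 9 of 25 alternatives (0.00609, without Pgr, to 0.323), multiciliated cells upward with the range as a covariate (0.0110, leaning either way elsewhere), prostaglandin genes by fry (0.0246), adipocytes with 50% removed (0.0158), ovarian genes upward without PR+/- replicate 4 (0.00568, but leaning downward without PRKO replicate 3 and with the range as a covariate, median -0.05) and growth factors without PRKO replicate 3 (0.0317). For adipocytes, the 50% filter drops the dim members Adipoq and Lep, whose log2 changes were 0.19 and 0.18. Where no construction is named, the cause was not tested. The table holds no background values, so how far dim signals limit these calls was not measured.

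With the replicate number as a replicate block, 1042 genes were called (254 rose, 788 fell), of which 853 were called without it, and the integrin list had an adjusted p of 0.0559, while no other list called without the block lost its call. It ended the calls of 4 of the 83 named genes and called the estrogen-responsive list (0.0376). The deviations of same-numbered arrays from their group means correlated over genes at 0.104, 0.125, -0.01, 0.129 and 0.159 for numbers 1 to 5, not all above 0.1, and the arrays of PR+/- replicates 1 and 3 correlated better with PRKO replicates 2 and 5 than with their own number. Those of PR+/- replicates 2, 4 and 5 correlated best with the PRKO array of their own number. The check for pairing was thus not met, but a weak pairing by number is neither shown nor excluded.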

Other observations

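The 9 genes of this paragraph were picked by hand, after their values were seen, from the 15 with the smallest p outside the lists and the named genes, and the other 6, not described here, also fell. Plpp3, a membrane lipid phosphatase that degrades lysophosphatidic acid, was 2.56-fold lower in PRKO oviducts (log2 -1.35 ± 0.076, SE, n = 5 against 5, limma adjusted p = 3.22e-07). Kcnj8, the pore subunit of an ATP-sensitive potassium channel of smooth muscle, fell by 1.44 ± 0.099, and Fxyd4, a regulator of the sodium pump, by 1.37 ± 0.098. Penk, the precursor of enkephalin peptides, was 2.38-fold lower, from a PR+/- log2 signal of 10.3. Col11a1, a minor fibrillar collagen outside the matrix list, fell by 1.22 ± 0.083, and Cdkn1c, an inhibitor of cyclin-dependent kinases, by 1.08 ± 0.074. Lrp2, the endocytic receptor megalin, fell by 1.42 ± 0.11, Tgfbr3, a coreceptor of transforming growth factor beta, by 0.95 ± 0.073, and Mcam, an adhesion molecule of muscle and endothelium, by 0.86 ± 0.074. Each was lower on all 5 PRKO arrays than on any PR+/- array.

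Ovarian transcripts were high on 1 array of each genotype. In PR+/- replicate 4 and PRKO replicate 3, the signal of Inha, the inhibin alpha subunit of granulosa cells, was 7.20 and 7.63, against 5.24 to 5.97 on the other arrays, and that of the oocyte gene Nlrp5 was 4.85 and 4.91, against 3.06 to 3.68. Without these 2 arrays, 562 genes were called in limma, of which 529 were among the 988.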
